A study of Mus musculus with 6 samples.

How the data were processed

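RNA from sorted acinar cells was depleted of ribosomal RNA and made into libraries with the NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2 and the genome build mm10, without saying what each was used for. The tool that gave the values used here, and its version, are not given in the sources used here.

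The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled to library size) for 50660 transcripts of 21949 genes, all protein-coding, in 6 libraries. Its cells are not valid FPKM as printed, so its unit was recorded as other. The design had assumed readable FPKM per gene, and its test (limma on log2 values) was kept on the values recovered as follows. From the values, a spreadsheet appears to have read the decimal point as a mark between groups of digits: between 1 and 1000 FPKM the mark is lost, so that 3 values a factor of 10 apart are written alike, and below 0.0001 the values are written too large. Values of 0, from 0.0001 to 1, and above 1000 were used as deposited. A lost mark touched 61293 transcript values (31.5% of those above 0), and 712 values in that range kept theirs.

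Each lost mark was placed from 2 sources, blind to the groups, with priors given below. The FPKM of a transcript should be a whole number of fragments over its effective length, and a library should lie near the gene's level in the other libraries. The first rests on values below 1 FPKM of genes with 1 transcript, which fixed in each library the number of fragments it was divided by (1534850, 7127650 and 5810520 for KRASG12D and 9262230, 12013800 and 11520200 for cerulein) and the length subtracted. With these, 79.9% to 82.9% of such values came out whole within 0.01 of a fragment. Transcript lengths came from the GENCODE M21 annotation of GRCm38; 553 transcripts had none, and 1570 were given a length that differed by a whole number. The sum of fragments over placed values was 26.7% to 111% of the number each library was divided by. Values whose mark stayed open are not in these sums, which are therefore too low. In KRASG12D replicate 1 the placed fragments alone exceeded that number (111%), and median ratio factors between the libraries were 0.953 to 1.02. The deposited values thus appear to have been scaled between libraries, and how is not given in the sources used here. The priors were a density of FPKM levels, from values whose mark was not lost, and shares of genes with 2 levels. These shares were 0.35 with 3 libraries at each level, all splits alike, and 0.15 with any libraries at either level. A value was placed where 1 position had a posterior of at least 0.95. Of 422 values whose mark had survived and was hidden for a check, 332 were placed and 331 of these were right. In simulated data, 71 of 39782 placed values (0.18%) were wrong. These data were built from the recovered levels and the fitted lengths and fragment sizes, and decoded with the same priors. Errors from a wrong length or a wrong model therefore cannot show in that share. Placement is less complete at high values: in the simulation 90.6% of values from 1 to 10 FPKM were placed, 68.7% from 10 to 100 and 46.9% from 100 to 1000.

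Transcript FPKM were summed per gene. Genes were tested where all 6 libraries were placed and at least 3 had 1 FPKM or more. Precision differs between libraries: 1 fragment was worth 652 FPKM divided by the effective length in nucleotides in KRASG12D replicate 1, and 83.2 in cerulein replicate 2. Values of 0 occur for broadly expressed genes in the shallow libraries and are given as listed at 0. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

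The groups (3 KRASG12D and 3 KRASG12D with cerulein libraries) come from the sample titles. The test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided) with Benjamini-Hochberg adjustment over all tested genes. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 3 tested members, and again with camera's estimated correlation and with fry; 41 lists, 14 of them markers of other cell types, were fixed with their members. The share of summed FPKM in digestive enzymes, at the best placement of every value, was compared by a two-sided exact permutation test. Decoding and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The groups, the design, the lists and the rule for named genes were chosen before the data were examined. The rule took, among genes past the adjusted p threshold with a mean of at least 5 FPKM in the higher group and no overlap between the groups, the 10 largest increases and 10 largest decreases; from each list that passed camera, the 3 members with the largest passing change in its direction and the 1 largest against it; and 27 genes whatever their values. It gave 78 genes, of which 62 could be tested; examples from each list are printed.

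The fits were tested on simulated data in which 200 of the genes changed, over the same placement: 60 of 6564 genes were called, 6 of them not simulated as changed (10%), and 0 in the wrong direction. Among genes that could be tested, the test called 18 of 20 lowered 8-fold, 15 of 27 lowered 4-fold, 4 of 27 lowered 2-fold, 3 of 19 raised 2-fold, 7 of 9 raised 4-fold and 7 of 8 raised 8-fold. With no list shifted 0 of 32 lists were called, and a list shifted by a log2 of 1 was called, also with an estimated correlation. Genes varied independently of each other in the simulation, so it cannot show how often lists of correlated genes are called falsely. In the data the estimated correlation was 0.62 for digestive enzymes and 0.92 for genes encoded in mitochondria.

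The labels give both groups the replicate numbers 1 to 3. Deviations of same-numbered libraries from their group means correlated across genes at 0.217, 0.106 and 0.108, all above the limit of 0.1 for taking the numbers as pairs. Libraries of unequal number reached 0.090 (KRASG12D 2 with cerulein 3) and 0.097 (KRASG12D 3 with cerulein 2), and the others were from -0.161 to -0.138, so the values set apart replicate 1 but hardly tell replicates 2 and 3 from each other; the labels do not say what a number marks. The fit with the number as a block was an alternative. Others were the pseudocount, the filter on low values, 4 scalings, limma's variance settings and library weights, a stricter threshold, each library left out in turn, other placements of the marks, voom on recovered fragments, and removal of trends with GC content and length. Count tests (DESeq2 or edgeR) were not run, since the table gives no readable counts. Coordinates are those of GENCODE M21 on GRCm38, 1-based. Values of genes whose mark stayed open in any library were left out of the tests. The cerulein dose is not reported, since its unit in the labels appears incomplete.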

Results

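RNA was sequenced from mouse pancreatic acinar cells that had been sorted by flow cytometry and carried an inducible KRASG12D allele with a YFP reporter under an acinar Cre driver. The 6 libraries formed 2 groups of 3: KRASG12D alone, and KRASG12D after cerulein, a secretagogue that causes pancreatitis, given as 7 injections per day, every other day, for 3 days with 1 day of recovery. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. The deposited table listed 50660 transcripts of 21949 protein-coding genes, summed here to gene FPKM. Most of its values from 1 to 1000 FPKM had lost their decimal mark, and a mark was placed again at a posterior of at least 0.95 for 38867 of the 47175 gene values concerned (82.4%). The table held no counts. In genes with 1 transcript, 79.9% to 82.9% of the values below 1 FPKM in each library lay within 0.01 of a whole number of fragments. The fragment size fitted to them put the fragments of placed values at 1707320, 4043210 and 4131340 in the KRASG12D libraries and 2476520, 4325220 and 4726010 in the cerulein libraries. Values whose mark stayed open are not counted, so these sums are too low. Of 8916 genes with at least 1 FPKM in 3 libraries, 6358 had every mark placed and were tested. In a simulation of this comparison over 6564 genes, 24.2% of genes raised 8-fold and 60.6% of genes lowered 8-fold could be tested, so many large changes may be missing. Simulated changes shifted the cerulein libraries alone from a shared level. Raised genes thus reached higher FPKM, where fewer marks are placed. The simulation therefore cannot tell whether increases are missed more often than decreases in the data.

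The comparison asked how pancreatitis alters acinar cells that already express oncogenic Kras. With cerulein, gene lists of acinar function were lower and lists of inflammation and matrix higher by the camera test with a preset correlation. None of them passed with an estimated correlation (adjusted p from 0.40 to 0.48), and markers of macrophages, neutrophils and fibroblasts were higher in the same libraries. Transcripts of digestive enzymes made up 69.3% ± 3.19 (SD, n = 3) of summed FPKM in KRASG12D libraries and 49.9% ± 6.64 (SD, n = 3) in cerulein libraries, a difference of -19.4 percentage points. These shares rest on the best placement of every lost decimal mark. Over placed values alone they were 77.0% and 64.2%, a difference of -12.8 points. With the lost marks of enzymes at one extreme of their possible places and those of all other genes at the other, the range was 11.5% to 83.5% in KRASG12D and 3.29% to 72.3% in cerulein libraries. These ranges overlap. At best placement the share was lower in all 3 cerulein libraries than in any KRASG12D library (two-sided exact permutation test, p = 0.10, the smallest that 3 against 3 allows). With libraries of equal replicate number taken as pairs, exact sign flips gave a two-sided p of 0.25, the smallest that 3 pairs allow. Over all genes, 1500 of 6358 changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 875 higher and 625 lower with cerulein. Of these, 993 changed at least 2-fold on the log2(FPKM + 1) scale, 623 higher and 370 lower.

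**Figure D1:**
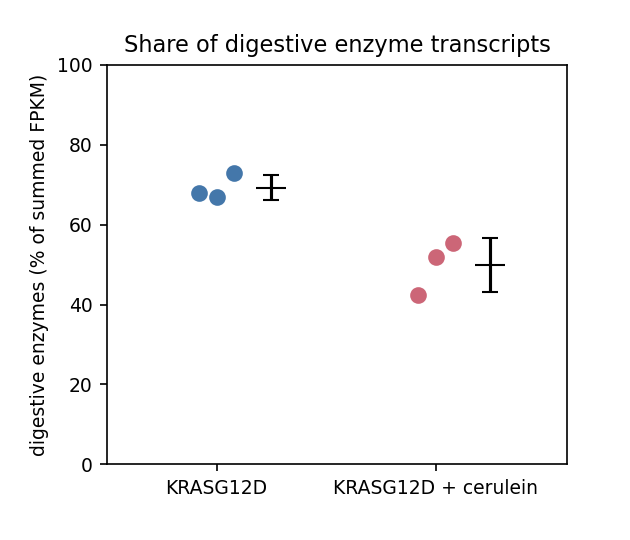
Share of summed FPKM in transcripts of digestive enzymes (vertical axis, percent) in each library of the 2 groups (horizontal axis). Points are libraries, and bars give the mean and SD of 3 libraries; KRASG12D libraries lie from 67.0% to 72.9% and cerulein libraries from 42.5% to 55.3%.

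Among genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups, Ly6a had the largest increase. Ly6a, which encodes the surface antigen Sca-1 (ENSMUSG00000075602, GRCm38 chromosome 15, 74994877 to 74998031), averaged 1.13 ± 0.731 FPKM in KRASG12D and 82.6 ± 38.1 FPKM in cerulein libraries (SD, n = 3), a log2 change of 5.21 with SE 0.40 (limma adjusted p = 1.0e-04). Cldn4, which encodes the tight junction protein claudin-4 (ENSMUSG00000047501, chromosome 5, 134945119 to 134946934), went from 3.79 ± 0.307 to 143 ± 39.7 FPKM (SD, n = 3), with a log2 change of 4.88 (limma adjusted p = 1.5e-05). Il1b, the cytokine interleukin-1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), went from 0.319 ± 0.211 to 23.3 ± 2.85 FPKM (SD, n = 3), with a log2 change of 4.21 (limma adjusted p = 1.5e-05). Emp1, the annexin genes Anxa2 and Anxa3, and Fhl3 rose with log2 changes of 4.66, 4.06, 3.96 and 3.81. Il1rn, which encodes the antagonist of the interleukin-1 receptor, was listed at 0, 0.235 and 0.307 FPKM in KRASG12D and at 13.0, 17.9 and 25.4 FPKM in cerulein libraries. Timp1, an inhibitor of matrix metalloproteinases, was listed at 0 in all 3 KRASG12D libraries and at 21.3, 9.60 and 19.96 FPKM in cerulein libraries. Retnlg, a gene of neutrophils, was listed at 0, 0.340 and 0 FPKM in KRASG12D and at 5.78, 9.76 and 41.6 FPKM in cerulein libraries. All 10 of these genes passed with limma adjusted p of 0.0018 or less.

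Sostdc1, which encodes a secreted antagonist of BMP and Wnt signalling (ENSMUSG00000036169, chromosome 12, 36314139 to 36318452), had the largest decrease by the same rule, from 31.9 ± 4.76 to 0.560 ± 0.301 FPKM (SD, n = 3), a log2 change of -4.41 with SE 0.24 (limma adjusted p = 1.5e-05). Klf15, a transcription factor of metabolic genes (ENSMUSG00000030087, chromosome 6, 90462576 to 90475238), went from 17.6 ± 3.95 to 0.776 ± 0.304 FPKM (SD, n = 3, log2 change -3.38, limma adjusted p = 7.7e-05). Klb, the co-receptor of FGF21 (ENSMUSG00000029195, chromosome 5, 65348314 to 65384007), went from 8.35 ± 1.66 to 0.402 ± 0.0735 FPKM (SD, n = 3, log2 change -2.72, limma adjusted p = 1.2e-04). The growth factor gene Bmp3, the claudin gene Cldn8, the GABA receptor subunit gene Gabra4, the mitochondrial carrier gene Slc25a35 and C2cd4b fell, with log2 changes of -2.82, -3.13, -2.82, -2.62 and -3.61. The enzyme genes Pnlip and Rnase1 complete the 10 largest decreases.

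**Figure D2:**
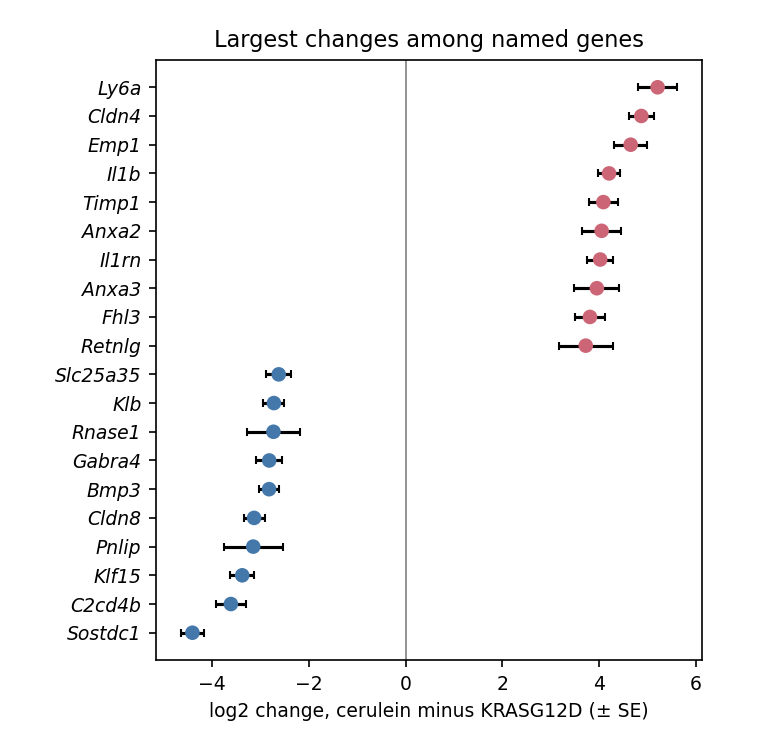
Log2 change between cerulein and KRASG12D libraries on the log2(FPKM + 1) scale (horizontal axis) for the 10 genes with the largest increase and the 10 with the largest decrease (vertical axis). Points are limma estimates from 3 libraries per group and bars are standard errors; changes span from -4.41 for Sostdc1 to 5.21 for Ly6a.

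Of 41 gene lists, 31 had at least 3 tested members, and 13 passed limma's camera test at a Benjamini-Hochberg adjusted p under 0.05, 8 upward and 5 downward. None passed when camera estimated the correlation between genes (0 of 31, and 3 at an unadjusted p under 0.05), and 19 passed limma's fry test of a shared direction. The fry count was 11 with the replicate numbers as a block, 11 without KRASG12D replicate 3, 9 without cerulein replicate 2 and 8 of 15 lists at a mean of at least 5 FPKM. Counts of genes are over tested members: 25 of 37 digestive enzymes, 9 of 18 acinar identity regulators and 8 of 27 unfolded protein response genes. For secretory genes, fibroblast markers and ribosomal proteins they were 14 of 30, 6 of 20 and 6 of 33. The other members had an open mark, were below the expression filter or were not listed. Of 25 tested digestive enzyme genes, 11 fell and 0 rose (13 and 0 when adjusted over the list alone), with a median log2 change of -1.502 (camera adjusted p = 1.9e-04, and adjusted p = 0.48 with an estimated correlation). This list also holds genes of proteins that are not enzymes, among them Spink1, Dmbt1 and Cuzd1. After quantile normalization, which gives each rank the same value in every library, the list's direction turned upward (camera adjusted p = 0.85, in a range of 1.1e-13 to 0.85 over the alternatives). Pnlip, pancreatic lipase (ENSMUSG00000046008, chromosome 19, 58652498 to 58681788), went from 32145 ± 8166 to 4030 ± 2323 FPKM (SD, n = 3, log2 change -3.15, limma adjusted p = 0.0055). Rnase1, pancreatic ribonuclease (ENSMUSG00000035896, chromosome 14, 51144998 to 51146785), went from 23880 ± 2256 to 3879 ± 1755 FPKM (SD, n = 3, log2 change -2.73, limma adjusted p = 0.0066), and Cuzd1, a zymogen granule protein, fell with a log2 change of -2.33. Cela1, elastase 1, had a log2 change of -2.09 (limma adjusted p = 0.030) that missed the threshold without KRASG12D replicate 1 (0.068), 2 (0.068) or 3 (0.11) or cerulein replicate 2 (0.12). After quantile normalization the log2 change of Cela1 was -0.07 (limma adjusted p = 0.85, in a range of 0.0035 to 0.85 over the alternatives). With no filter on low values Pnlip, Rnase1 and Cela1 missed the threshold (limma adjusted p = 0.056, 0.060 and 0.16). Cpa1, carboxypeptidase A1, did not pass, at 34249 ± 7809 against 10961 ± 4711 FPKM (SD, n = 3, log2 change -1.73, limma adjusted p = 0.070). It passed under 10 alternatives, among them limma without a trend (0.0086), library weights (0.030) and a mean of at least 5 FPKM (0.033), in a range of 0.0086 to 0.92 over all alternatives. Amylase and trypsin genes have near-identical copies between which reads can be split, so their single values are uncertain.

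Acinar identity regulators fell as a group: 5 of 9 tested were lower and 0 higher (6 and 1 when adjusted over the list alone), with a median log2 change of -1.24 (camera adjusted p = 0.0031, and adjusted p = 0.40 with an estimated correlation). Nr5a2, a nuclear receptor that sustains the acinar programme (ENSMUSG00000026398, chromosome 1, 136842571 to 136960448), went from 19.1 ± 1.74 to 4.48 ± 1.77 FPKM (SD, n = 3, log2 change -1.93, limma adjusted p = 0.0016). The muscarinic receptor gene Chrm3 and the transcription factor gene Foxa2 fell with log2 changes of -1.498 and -1.42. Of 8 genes of the unfolded protein response, 4 fell and 0 rose, also when adjusted over the list alone (median log2 change -0.77; camera adjusted p = 0.0026, and adjusted p = 0.40 with an estimated correlation). Among them were Syvn1, the ubiquitin ligase of ER-associated degradation (24.1 ± 7.68 to 3.14 ± 0.478 FPKM, SD, n = 3), the co-chaperone gene Dnajc3 (57.6 ± 11.7 to 12.9 ± 2.48 FPKM, SD, n = 3) and the ER stress sensor gene Atf6 (log2 change -1.33). Of 14 genes of the secretory pathway and translocon, 3 fell and 0 rose, again also over the list alone (median log2 change -0.57; camera adjusted p = 0.0097, and adjusted p = 0.46 with an estimated correlation). Its signal peptidase subunit gene Spcs2 and translocon gene Ssr1 had log2 changes of -1.60 and -1.37. When each library was scaled to the same sum, the secretory list missed the threshold (camera adjusted p = 0.083, in a range of 3.4e-04 to 0.46 over the alternatives), as did Chrm3 (limma adjusted p = 0.062), Foxa2 (0.21), Atf6 (0.20), Spcs2 (0.069) and Ssr1 (0.23).

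Genes of NF-kB signalling and inflammatory cytokines rose: 11 of 14 tested were higher and 0 lower (14 and 0 when adjusted over the list alone), with a median log2 change of 1.54 (camera adjusted p = 3.5e-08, and adjusted p = 0.40 with an estimated correlation). Besides Il1b, the cytokine gene Lif went from 0.318 ± 0.0361 to 9.63 ± 0.849 FPKM and Tnfaip3, which encodes the NF-kB inhibitor A20, from 2.05 ± 0.307 to 18.5 ± 5.004 FPKM (SD, n = 3). Of 12 genes of matrix and its remodelling, 8 rose and 0 fell (10 and 0 when adjusted over the list alone, median log2 change 1.19, camera adjusted p = 1.3e-04, and adjusted p = 0.40 with an estimated correlation). The list was drawn up for epithelium, but which cells made these transcripts was not tested. Besides Timp1, the genes that rose included the integrin gene Itgb6, with a log2 change of 1.87. Plaur, the urokinase receptor gene, was listed at 0, 0.107 and 0.653 FPKM in KRASG12D and at 3.40, 3.61 and 9.95 FPKM in cerulein libraries. Of 6 genes of MHC class I and antigen processing, 4 rose and 0 fell, also over the list alone (median log2 change 1.05; camera adjusted p = 0.014, and adjusted p = 0.43 with an estimated correlation), among them H2-Q4 with a log2 change of 1.23. This list missed the threshold after scaling to the same sum (camera adjusted p = 0.079) and with marks placed at a posterior of at least 0.99 (0.083), in a range of 0.0010 to 0.43 over the alternatives. Of 12 S phase genes, 5 rose and 0 fell, also over the list alone (median log2 change 0.74; camera adjusted p = 0.0041, and adjusted p = 0.46 with an estimated correlation). They included the replicative helicase genes Mcm6 and Mcm3, with log2 changes of 2.06 and 1.11. Macrophage, neutrophil and fibroblast markers were higher in the same libraries, with median log2 changes of 1.51, 1.79 and 1.15.

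Of 16 genes of cholesterol synthesis, 4 rose and 0 fell (7 and 1 when adjusted over the list alone; median log2 change 0.60; camera adjusted p = 0.044, and adjusted p = 0.47 with an estimated correlation), with a log2 change of 1.07 for Dhcr24, which encodes a reductase of sterol synthesis. This list missed the threshold with the replicate numbers as a block (camera adjusted p = 0.054, in a range of 0.023 to 0.47 over the alternatives) and without KRASG12D replicate 2 (0.062) or 3 (0.061) or cerulein replicate 3 (0.098). Of 5 genes encoded in mitochondria, 1 was lower and 0 higher (5 and 0 when adjusted over the list alone; median log2 change -1.61; camera adjusted p = 0.020, and adjusted p = 0.48 with an estimated correlation), and the list missed the threshold without KRASG12D replicate 2 (0.073) or 3 (0.061).

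**Figure D3:**
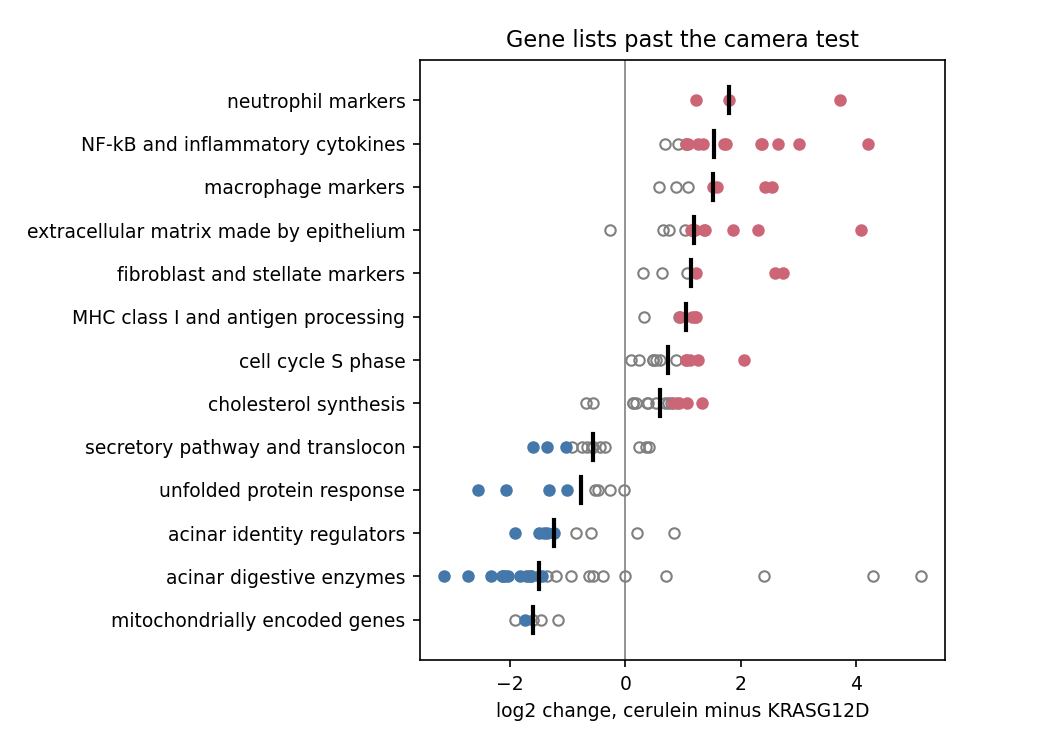
Log2 change between cerulein and KRASG12D libraries on the log2(FPKM + 1) scale (horizontal axis) of each tested gene in the 13 lists that passed the camera test (vertical axis). Filled points are genes past the adjusted p threshold in the list's direction, open points are the other genes and black bars are list medians, from -1.61 for genes encoded in mitochondria to 1.79 for neutrophil markers; the enzyme list's direction turned upward after quantile normalization.

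Markers of other cell types that the sorted fraction can hold were higher with cerulein for leukocytes and fibroblasts. Of 7 macrophage markers, 4 rose and 0 fell (5 and 0 when adjusted over the list alone; camera adjusted p = 0.0031, and adjusted p = 0.43 with an estimated correlation). Cd68 went from 1.30 ± 0.0774 to 5.98 ± 1.43 FPKM (SD, n = 3), and Ly6c2 was listed at 0 in all KRASG12D libraries and at 3.33, 3.82 and 8.45 FPKM in cerulein libraries. All 3 tested neutrophil markers rose, also over the list alone (camera adjusted p = 0.0041, and adjusted p = 0.43 with an estimated correlation). S100a8 was listed at 0 in KRASG12D and at 1.88, 2.53 and 3.09 FPKM in cerulein libraries. Of 6 fibroblast and stellate markers, 3 rose and 0 fell (4 and 0 when adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.48 with an estimated correlation), and the call was lost without KRASG12D replicate 1 (0.054) or 3 (0.051) or cerulein replicate 1 (0.069). With every gene at its best placement, 4 of 15 fibroblast markers were higher and 0 lower, with a median log2 change of 1.99 (camera adjusted p = 2.2e-04, and adjusted p = 0.41 with an estimated correlation). Postn, the matrix protein periostin, stood at 20.2, 7.47 and 3.78 FPKM in cerulein replicates 1, 2 and 3 and at 0.432 ± 0.185 FPKM (SD, n = 3) in KRASG12D. Ptprc, the leukocyte antigen CD45, rose from 0.868 ± 0.459 to 13.6 ± 7.52 FPKM (SD, n = 3, log2 change 2.85, limma adjusted p = 0.0011). Both tested MHC class II genes rose, with a median log2 change of 1.29. At the best placement of every gene 5 of 6 were higher (camera adjusted p = 0.0042, and adjusted p = 0.20 with an estimated correlation). Islet markers (1 of 3 higher, camera adjusted p = 0.30) and mature duct markers (1 of 7 lower, camera adjusted p = 0.40) did not pass. No test was possible for markers of T and NK cells, B and plasma cells, tuft cells, red blood cells, neural cells or mesothelial cells and adipocytes (0 with all marks placed and at least 1 FPKM in 3 libraries). The 1 tested marker of mast cells and eosinophils and the 1 of endothelial cells did not pass (log2 changes -0.05 and 0.54).

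**Figure D4:**
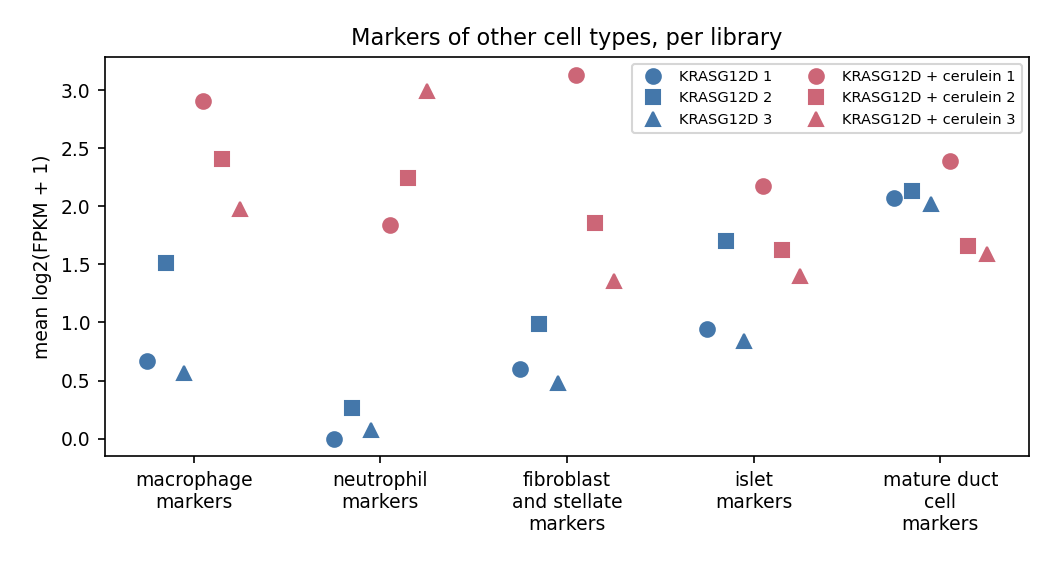
Mean log2(FPKM + 1) over the tested markers (vertical axis) of 5 other cell types (horizontal axis) in each library. Points are libraries; fibroblast markers stand highest in cerulein replicate 1 (3.13) and neutrophil markers in cerulein replicate 3 (3.00), and mature duct markers overlap between the groups.

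Kras itself averaged 4.26 ± 1.67 FPKM in KRASG12D and 10.3 ± 3.88 FPKM in cerulein libraries (SD, n = 3), a log2 change of 1.09 with SE 0.33 (limma adjusted p = 0.041). Its libraries overlapped (3.999, 6.04 and 2.73 against 5.94, 11.7 and 13.3 FPKM), and the call was lost without KRASG12D replicate 1 (adjusted p = 0.068) or 3 (0.15) or cerulein replicate 2 (0.14) or 3 (0.15). Over all alternatives its adjusted p ranged from 4.4e-04 to 0.15. Tff2, a trefoil factor, fell from 1537 ± 198 to 316 ± 126 FPKM (SD, n = 3, log2 change -2.35, limma adjusted p = 0.0028). The duct transcription factor gene Hnf1b had a log2 change of -1.26 (limma adjusted p = 0.016), which missed the threshold without KRASG12D replicate 3 (0.063) or cerulein replicate 2 (0.055) or 3 (0.061). Hnf1b also missed it when each library was scaled to the same sum (log2 change -0.59, limma adjusted p = 0.31), when scaled without enzymes and genes encoded in mitochondria (0.064) and with no filter (0.052). Mki67, a marker of cycling cells, had a log2 change of 1.27 (limma adjusted p = 0.026), with 0.057 and 0.082 without KRASG12D replicates 1 and 3 and 0.083 and 0.074 without cerulein replicates 1 and 2. It also missed the threshold with no filter (0.087) and with a pseudocount of 0.1 (0.051). Sox9, Dusp6 and Ddit3 did not pass (log2 changes -0.49, 0.52 and -0.52; limma adjusted p = 0.12, 0.23 and 0.37), and Sox9 and Ddit3 had positive changes when each library was scaled to the same sum. Dusp6 passed upward with that scaling (log2 change 1.44, limma adjusted p = 0.014, in a range of 0.014 to 0.54 over the alternatives), and Ddit3 passed downward with library weights (log2 change -0.83, limma adjusted p = 0.039, in a range of 0.039 to 0.75).

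For 11 genes named in advance a decimal mark stayed open in at least 1 library, and no test was made. Krt19, a keratin of duct cells, stood at 89.8, 96.5 and 115 FPKM in cerulein libraries, with its KRASG12D values open. The acinar transcription factor genes Bhlha15 (31.8, 32.2 and 57.1 FPKM) and Ptf1a (20.7, 39.96 and 34.2 FPKM), and the immediate early gene Fos (242, 193 and 261 FPKM), had placed values in KRASG12D libraries alone. Cd44 stood at 3.51, 2.09 and 1.36 FPKM in KRASG12D and at 23.9 and 27.1 FPKM in cerulein replicates 1 and 2. Lcn2, lipocalin-2, was listed at 0 and 0.590 FPKM in KRASG12D replicates 1 and 2 and stood at 49.1, 30.4 and 18.7 FPKM in cerulein libraries. Reg3b, a regenerating protein, stood at 298 FPKM in KRASG12D replicate 1 and at 1686 and 2417 FPKM in cerulein replicates 1 and 3. The chaperone gene Hspa5 stood at 142 and 238 FPKM in KRASG12D replicates 1 and 2 and at 98.1 and 86.7 FPKM in cerulein replicates 2 and 3. The collagen gene Col1a1, a fibroblast marker, stood at 0.338 FPKM in KRASG12D replicate 1 and at 59.3 and 33.6 FPKM in cerulein replicates 2 and 3. Spp1 stood at 81.3 and 47.3 FPKM in KRASG12D replicates 1 and 3 and at 91.3 FPKM in cerulein replicate 3. The insulin gene Ins2 had no placed value. Il33, Dclk1, Muc6, Onecut2 and Pecam1 were below the expression filter.

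The remaining lists did not pass the camera test in the main analysis. Those with positive direction were glycolysis (5 of 8 genes higher, 1 lower, camera adjusted p = 0.064), epithelial to mesenchymal transition (2 of 3 higher, 0.064), G2 and mitosis (1 of 3 higher, 0.079), YAP targets (3 of 10 higher, 0.095), duct and metaplasia genes (5 of 10 higher, 1 lower, 0.11), interferon response (1 of 7 higher, 0.16) and ERK pathway targets (5 of 16 higher, 2 lower, 0.19). Cytosolic ribosomal proteins (0 of 6, camera adjusted p = 0.24), p53 targets (1 of 9 higher, 0.24), immediate early genes (3 of 14 higher, 2 lower, 0.29), autophagy (4 of 13 higher, 1 lower, 0.31) and NRF2 targets (5 of 15 higher, 3 lower, 0.31) were also positive. Amino acid metabolism (2 of 15 higher, 5 lower, camera adjusted p = 0.31) and Notch and Wnt targets (1 of 6 higher, 0.34) had negative direction. Several of these lists passed under alternatives, by camera with the preset correlation or by fry. With an estimated correlation none passed under any alternative. At the best placement of every gene that camera adjusted p was 0.20 for duct and metaplasia genes and for epithelial to mesenchymal transition. It was 0.22 for glycolysis and YAP targets and 0.41 for G2 and mitosis. Duct and metaplasia genes passed under 7, with a camera adjusted p of 0.048 after scaling to the same sum, 0.017 at a mean of at least 5 FPKM and 5.5e-04 at the best placement of every gene. Epithelial to mesenchymal transition passed under 9, with 0.048 after scaling to the same sum, 1.1e-04 at best placement and 0.027 without cerulein replicate 1. Glycolysis passed under 6, with 0.0035 at best placement and 0.029 without KRASG12D replicate 1. YAP targets passed under 6, with 0.026 at best placement and 0.037 without cerulein replicate 3. G2 and mitosis passed under 4, with 0.026 at best placement and 0.018 without KRASG12D replicate 2. Ribosomal proteins passed after scaling to the same sum (0.012) and without cerulein replicate 1 (0.0048), and interferon response with no filter (0.0057). By fry alone, p53 targets (0.0028), autophagy (0.016), ERK pathway targets (0.026) and NRF2 targets (0.036) passed. Adjusted over the list alone, the counts differed for G2 and mitosis (3 higher), autophagy (4 higher, 2 lower), NRF2 targets (6 higher, 3 lower) and amino acid metabolism (3 higher, 6 lower). Nuclear genes of oxidative phosphorylation (0 of 13, 0.79) had a negative test direction with a median of 0.06 and a mean of 0.01, and gastric genes (1 of 3 higher, 1 lower, 0.96) a negative direction with a median of -0.41 and a mean of 0.13. Of the genes for regenerating and acute phase proteins, 1 of 2 was higher, too few for the test. At the best placement of every gene, 5 of 14 were higher and 0 lower (camera adjusted p = 0.028, and adjusted p = 0.22 with an estimated correlation). With placement knowing the groups 3 of 3 were higher (0.0054 and 0.22).

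The groups did not overlap in 2559 of 6358 genes (40.2%), where chance gives 10% on average. Genes vary together, so the share in a single split can lie far from that average. The prior for 2 levels with 3 libraries at each may also favour such patterns, so the comparison is not a test. The count of changed genes fell to 972 without KRASG12D replicate 3, 937 without cerulein replicate 2 and 959 without cerulein replicate 3 (lower genes 372, 351 and 366). Scaling each library to the same sum moved the share of higher genes from 58.3% to 96.5% and the median log2 change of all genes from 0.06 to 0.88, and scaling without enzymes and genes encoded in mitochondria moved them to 74.6% and 0.21.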

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

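The placements of decimal marks other than the main one, voom and the removal of GC content and length trends were chosen after seeing the data, as were the enzyme share over placed values and its sign flips within pairs; the other alternatives here were fixed beforehand. Of 58 named genes past the threshold, 41 stayed past it in the same direction under every alternative in which they were tested; over all pairs of such a gene and an alternative, 1426 of 1517 kept the call, 91 missed the threshold and 0 turned. For the 13 lists that passed, 324 of 365 pairs kept the call, 40 missed the threshold and 1 turned; all 13 missed it with an estimated correlation, where 0 lists passed (3 at an unadjusted p under 0.05; 19 by fry, falling to 11 with the replicate block or without KRASG12D replicate 3 and to 9 without cerulein replicate 2), and acinar identity, the unfolded protein response, S phase, NF-kB signalling, macrophage and neutrophil markers missed it under no other alternative. The cause was not tested for the changes below, except where fewer genes or libraries, a stricter threshold or the scaling itself gives it.

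Against 1500 changed genes (875 higher, 625 lower), the count was 469 (215, 254) among 1783 genes with a mean of at least 5 FPKM, 2907 (2805, 102) after scaling to the same sum, 2433 (1408, 1025) with library weights and 737 (466, 271) at an adjusted p under 0.01. Genes changed at least 2-fold numbered 2714 (2619 higher, 95 lower) scaled to the same sum, 333 (145, 188) at a mean of at least 5 FPKM, 632 (411, 221) at a posterior of at least 0.99, 1553 (874, 679) by voom and 1493 (946, 547) at best placement knowing the groups. Lower genes numbered 333 after scaling without enzymes and genes encoded in mitochondria and 410 at a posterior of at least 0.99. Leaving out 1 library gave 937 to 1641 genes (586 to 959 higher, 351 to 682 lower) and 10 to 14 lists. Lists past the threshold numbered 20 with no filter and 5 at a mean of at least 5 FPKM. The difference in enzyme share ranged from -22.1 to -15.7 percentage points with a library left out, and was -12.8 over placed values and -20.1 without genes encoded in mitochondria. Kras kept its direction and missed the threshold with a pseudocount of 0.1 (log2 change 1.25, adjusted p = 0.052), and, at 1.09, with no filter (0.099), at the best placement of every gene (0.075; 0.065 knowing the groups) and from whole fragments alone (0.052); with a library left out its log2 change ranged from 0.87 to 1.41.

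With the replicate number as a block, 1692 genes (1012 higher, 680 lower) and 12 lists passed; cholesterol synthesis missed the threshold (adjusted p = 0.054), and no other limma or camera call changed for a named gene or list. Other list calls were lost for matrix genes (0.10), the secretory pathway (0.051) and genes encoded in mitochondria (0.051) at a mean of at least 5 FPKM, for the secretory pathway at a posterior of 0.99 (0.22), for genes encoded in mitochondria by quantiles (0.059) and fry (0.12), for fibroblast markers scaled to the same sum (0.10), by voom (0.050) and by fry (0.11), and for cholesterol synthesis scaled to the same sum (0.087), by quantiles (0.074), with weights (0.056), at best placement (0.074; 0.13 knowing the groups) and without GC content and length trends (0.067). Quantile normalization, which gives each rank one value in all libraries, turned the enzyme list (0.85). Of pairs of a list that had not passed and an alternative, 39 of 504 passed. The other reversals were of results that had not passed. Scaling to the same sum turned Ddit3 (log2 change 0.30) and Sox9 (0.39). Adjusted p of turned lists were, for gastric genes, 0.97 with a pseudocount of 0.1, 0.99 at a mean of at least 1 FPKM, 0.28 at best placement (0.19 knowing the groups), 0.28 by fry and 0.91, 0.82 and 0.94 without KRASG12D replicates 2 and 3 and cerulein replicate 2 (the 6 fits with a library left out, turned or not, gave 0.54 to 0.94); for oxidative phosphorylation, 0.99 at a mean of at least 5 FPKM, 0.20 scaled to the same sum, 0.92 scaled without enzymes, 0.91 by quantiles, 0.88 with weights, 0.99 at best placement knowing the groups, 0.93 by fry and 0.52 without cerulein replicate 1 (0.44 to 0.92 over the 6 fits, turned or not); for amino acid metabolism, 0.92 at a posterior of 0.99; for mature duct markers, 0.94 at both best placements; and, at a mean of at least 5 FPKM, 0.32 for NRF2 targets and 0.97 for immediate early genes. All genes are protein-coding. Count tests were not run.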

Other observations

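The genes in the first 2 paragraphs were chosen after their values were seen, and all tests of explanations below were chosen after the result was seen. They are single genes and stand for no tested group. Egf fell from 18.1 ± 7.06 to 3.05 ± 1.29 FPKM (SD, n = 3; log2 change -2.24; limma adjusted p = 0.0018), while Egfr, which encodes its receptor, was at 2.74 ± 0.474 and 7.01 ± 2.76 FPKM (log2 change 1.05; limma adjusted p = 0.020; 0.076 without KRASG12D replicate 3 and 0.076 without cerulein replicate 3). The insulin receptor gene Insr, Deptor, which encodes an inhibitor of mTOR, and Vipr2, a receptor gene for vasoactive intestinal peptide, fell with log2 changes of -1.64, -1.90 and -2.30, of which Insr was -0.88 after scaling to the same sum (limma adjusted p = 0.062). Fosl1, a subunit of AP-1, was listed at 0, 0.0928 and 0 FPKM in KRASG12D and at 6.34, 14.2 and 20.5 FPKM in cerulein libraries. Among targets of ERK signalling, Dusp4, Epha2 and Etv4 rose (log2 changes 1.65, 1.80 and 1.49) and Etv5 fell (-1.41, limma adjusted p = 0.0069, and 0.20 after scaling to the same sum). Etv4 was listed at 0, 0.131 and 0 FPKM in KRASG12D and at 2.27, 1.64 and 1.88 FPKM in cerulein libraries. Ctse, cathepsin E, rose from 0.378 ± 0.351 to 11.2 ± 3.17 FPKM (SD, n = 3; log2 change 3.14; limma adjusted p = 1.6e-04), while the trefoil gene Tff2 of the same gastric list fell.

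Of single genes for actin-binding proteins, Flna went from 2.46 ± 1.11 to 22.4 ± 7.50 FPKM, Actn4 from 7.68 ± 2.23 to 26.8 ± 1.89, Cttn from 3.95 ± 1.28 to 13.6 ± 1.04 and Arpc1b from 7.64 ± 3.90 to 29.1 ± 2.55 (SD, n = 3), with limma adjusted p from 6.9e-04 for Flna to 0.0027 for Arpc1b. Members of the NRF2 list moved apart: the sulfiredoxin gene Srxn1, the malic enzyme gene Me1 and the thioredoxin reductase gene Txnrd1 rose (log2 changes 1.84, 1.83 and 1.27), and Cat, catalase, fell (-1.14; limma adjusted p = 0.011, and 0.54 after scaling to the same sum). In amino acid metabolism, the mitochondrial folate enzyme gene Aldh1l2 and the glutamine transporter gene Slc38a5 fell (log2 changes -2.15 and -2.31), while Mthfd1l, another mitochondrial folate enzyme gene, and the glutaminase gene Gls rose (1.07 and 1.19), Gls with a limma adjusted p of 0.066 by voom. Of glycolysis, Pfkfb3, Hk1 and the lactate exporter gene Slc16a3 rose (log2 changes 1.56, 1.31 and 1.38), and Pdk1, which encodes an inhibitor of pyruvate dehydrogenase, fell (-1.253; limma adjusted p = 0.0028, and 0.14 after scaling to the same sum). Of the 31 genes singled out after seeing their values, not all of them printed here, 22 stayed past the threshold under every alternative, and 0 turned.

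The 623 genes at least 2-fold higher included markers of macrophages, neutrophils and fibroblasts. For the markers that could be tested, fewer acinar cells in the sort with an unchanged mix of the others is argued against, mainly by duct markers. The 16 markers of those types rose by a mean log2 of 1.62 and 10 islet and duct markers by 0.04, a difference of 1.585 (largest SD between libraries of a group 0.17). The 0.04 pools 3 islet markers, with a mean log2 change of 0.57, and 7 duct markers, with -0.195. The islet rise goes partly with the explanation. Only 7 of 16 duct markers were tested, and Krt19 was not, since its KRASG12D marks stayed open. At the best placement of every gene the duct list turned upward, with a median log2 change of 0.22 over 9 markers. There the median was 0.15 over 11 islet markers and 1.51 over 13 macrophage markers. RNA of macrophages, neutrophils and fibroblasts in the sorted fraction may account for their markers, in spite of the acinar sort. This was counted over markers placed in all 3 cerulein libraries and above a low floor, tested or not. In cerulein replicate 1, 10 of 10 fibroblast markers were highest, as were 11 of 14 macrophage markers. In cerulein replicate 3, 5 of 5 neutrophil markers were highest. Whether such RNA is the source of all 623 genes stays open. Of the 623, 36.4% (227 of 623) lay within 1.5 times across the cerulein libraries, against 1 of the 10 markers among them. In cerulein replicate 2, 135 were highest (51 by more than 1.25 times), against 0 of those 10 markers. Too few markers passed the same selection to exclude it, and cerulein acting on the acinar cells stays open too; a mix of types with opposite orders can be flat, and other genes of those cells need not follow the markers.

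For the fall of the digestive enzymes, dilution of acinar RNA by one factor as the only cause is argued against. Of 25 tested members of the enzyme list, 6 differed in their change from the median of the list taken within each library, at an adjusted p under 0.05 in limma. Of these, 2 fell further (Pnlip and Rnase1) and 4 less (Pnliprp1, Dmbt1, Ctrb1 and Spink1). Dmbt1 and Spink1 are not enzymes, and Ctrb1 has a near-identical copy, so its value is uncertain. Dilution behind a part of the fall stays open: the test cannot exclude it, and leukocyte and fibroblast markers rose in the same libraries. Reads shared between near-identical copies are argued against by a median log2 change of -1.78 over 16 list members without such a copy (-3.15 to -0.00, 11 of 16 lower), against -0.38 over 9 with one (0 lower). The low depth of KRASG12D replicate 1 is argued against, as the share of summed FPKM still differed by -20.04 percentage points without it. A lower enzyme output of acinar cells after cerulein stays a hypothesis, found and tested on the same libraries, and these tests cannot tell it from partial dilution. The enzyme list also turned upward after quantile normalization (camera adjusted p = 0.85) and missed the threshold with an estimated correlation (camera adjusted p = 0.48).

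Among genes changed at least 2-fold, 62.7% were higher, but 43.5% (145 of 333) at a mean of at least 5 FPKM and 56.3% by voom. The low depth of KRASG12D replicate 1 is argued against, since the share was 62.4% without that library. Whether a trend with GC content and transcript length contributes stays open. The share was 53.01% after its removal, but the removal also centred every library on the same mean over genes. Centring by itself can move the share and was not run alone. The log2 change correlated across genes, which are not independent replicates, at 0.13 with GC content and -0.12 with length. The part of the scaling between libraries stays open, since the share was 50.6% after quantile normalization, which gives all libraries one distribution, 61.8% with median ratios, 75.3% scaled without enzymes and genes encoded in mitochondria and 96.5% scaled to the same sum. A biological excess of either direction stays open too.

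The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1500 genes, as 1 of the 10, and the highest other 1; for lists the real split gave 13, as 1 of the 10, and the highest other 12, with KRASG12D replicate 1 beside cerulein replicates 1 and 2. Among the 4 splits that part all 3 pairs of equal numbers, the others gave 0 genes and at most 8 lists.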
